A study of Mus musculus with 62 samples.

How the data were processed

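RNA from whole hearts was measured in 62 libraries of 12 groups, 3 arms (CAC, NCAC and Con) at weeks 2, 4, 6 and 8. Per the labels' protocols RNA was extracted with Trizol, libraries were made with a stranded mRNA kit and sequenced on a NovaSeq instrument. Per the submitters' processing notes the reads were mapped to mm10, and the aligner, counting tool and annotation were not given in the sources used here. The authors deposited the values as TPM (transcript abundance scaled to a fixed total per library) for 47643 gene symbols, of which 24270 were 0 in every library. Groups and replicate numbers were read from the sample labels, and every column belonged to a sample. The labels name the strain as C57BL6/J while the design text names nude mice, and the protocol text mentions a 3-week time point of another tumour model that matches no sample. The labels give no batch or date.

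TPM is a share of each library, so a change in abundant transcripts shifts all other genes. Read depth was not given and was recovered from the smallest step between TPM values, with 70.0 to 70.8% of values falling within 0.05 reads of a whole number, where 10% would by chance. Gene coordinates and types were joined by symbol from GENCODE M21 (45134 symbols matched), whose version is assumed and not stated by the authors.

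The choices in this paragraph were fixed before the data were examined, except where said. Values were transformed as log2(TPM + 1), and genes with at least 1 TPM in at least 5 libraries were kept (12543). Group means were fitted over all 62 libraries with limma 3.58.1 (limma-trend) in R 4.3.3 with the package data.table (version 1.17.8), for 12 pairwise comparisons and 3 differences between weeks. P-values were adjusted within each comparison by Benjamini-Hochberg, with a threshold of 0.05. Of 43 gene lists written by hand, 37 had at least 5 measured members and were tested with limma's camera at a preset correlation of 0.01, adjusted over 444 tests, and again with an estimated correlation. Counts within a list were also taken with p-values adjusted over the list alone. Sharing of calls between weeks was counted against the number expected of independent lists. Figures were drawn with Python 3.11.15, matplotlib 3.10.9, pandas 2.3.3 and numpy 2.4.6.

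Genes were named by a rule. It took the 6 called genes with the largest rise and the 6 with the largest fall in each pairwise comparison, with at least 1 TPM in a group and with group ranges apart or at least 4 of 5 (6 of 7) libraries beyond the other group's median, leaving out predicted genes and pseudogenes. It also took up to 4 members with the smallest p of each described list, every called member where 5 or fewer were called, a panel of 16 cardiac, atrophy, matrix and clock genes at week 8, and the 4 largest rises and falls for differences between weeks. Mlana, Dct, Gdf15 and Gm2000 were chosen after their values were seen, as were the lists described.

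Alternatives fixed in advance were a pseudocount of 0.1, no filter (23373 genes), a stricter filter of 5 TPM (8788 genes), median-of-ratios rescaling over 8623 genes, rescaling without mitochondrially encoded and haemoglobin genes, array quality weights, a replicate block, a fit on the compared groups alone and leaving out each library in turn. After the data were seen, leaving out Con week 4 replicate 2, alone, with rescaling over 10432 genes (the rescaled refit) or with CAC week 8 replicate 3, and limma's voom on recovered reads (12126 genes) were added. The degraded library stayed in the reported fit because that fit was fixed in advance. Apart from voom on the recovered reads, tools for counts were not used because the values are TPM.

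The fit was tested on simulated data with 200 of 12543 genes changed. The simulated noise was normal, independent between genes and of equal spread in all libraries. It held no degraded library and no shift of TPM shares, so false calls from these were not measured. At week 8 it called 43.3, 94 and 98.5% of genes changed by 0.5, 1 and 2 on the log2 scale and 4 unchanged genes, and without the degraded library 86.6% of those changed by 0.5. No 2 libraries of a group were as alike as repeated counting of the same RNA would be. Group labels were also exchanged between libraries up to 100 times per comparison.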

Results

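Hearts of mice were profiled by RNA sequencing at 4 times after tumour cell injection. The animals had received melanoma cells that cause cachexia (CAC), a wasting of muscle and fat that accompanies some tumours, melanoma cells that do not (NCAC), or a mock injection (Con). The design follows the heart as cachexia progresses. CAC and NCAC differ in the injected melanoma cells as well as in the wasting, so the design does not separate cachexia from the cell line. At 2, 4, 6 and 8 weeks each arm had 5 libraries, except CAC at week 8 with 7, which gave 62 libraries in 12 groups. The labels call them biological replicates, and the sample titles give each library its own heart number. The p-values measure the spread between these libraries. Heart numbers run without gaps except in CAC at week 8, where some are absent. Whether hearts were left out of that group could not be told.

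The deposited values are TPM, shares of each library, and 12543 gene symbols reached 1 TPM in at least 5 libraries and were tested. Reads recovered from the steps of the TPM values lay between 25.3 and 49.1 M per library, with a median of 46.1 M. The shallowest libraries were in CAC at week 2, with 38.3 ± 9.43 M reads (SD, n = 5). Mitochondrially encoded transcripts held 49.3 to 61.1% of TPM in 61 libraries and 89.1% in Con week 4 replicate 2. That library had 612 TPM of the myosin heavy chain gene Myh6, against 3419 to 8033 in the others, and is called degraded here. Fold changes are differences of means on the log2(TPM + 1) scale, which understates the change of low genes. Adjusted p-values of single genes come from limma and are written limma adjusted p, and those of gene lists come from limma's camera test and are written camera adjusted p, both adjusted by Benjamini-Hochberg. Camera compares the members of a list with all other tested genes. Its direction down can therefore mean a smaller rise than the rest rather than a fall. Genes past the 0.05 threshold are said to rise or fall, or to be called. Because the degraded library widens the spread that all groups share, the number of genes called in each comparison is also given after leaving it out and rescaling every library by the median of ratios, called the rescaled refit.

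At week 8 Serpina3n, a secreted protease inhibitor of the acute phase, stood at 1854 ± 904 TPM in CAC (SD, n = 7) and 2.43 ± 0.614 TPM in Con (SD, n = 5). It lies on chromosome 12 at 104406729 to 104414329, plus strand (GENCODE M21, the mm10 build). Its log2 fold change was 8.54 (SE 0.61, limma adjusted p = 1.23e-16), with 7 of 7 CAC libraries above all Con libraries. Lcn2, an iron-binding protein released in inflammation, rose from 0.853 ± 0.318 to 239 ± 116 TPM, and the metallothionein gene Mt2 from 20.9 ± 13.8 to 1848 ± 1006 TPM. The chemokine gene Ccl8 rose by 5.59, the serum amyloid gene Saa3 by 4.87 and Serpina3m by 4.54 on the log2 scale. Serpina3, Saa and metallothionein genes belong to families of similar copies whose reads the counting could split, so the value of a single member is uncertain. The largest falls were in Mylk4, a myosin light chain kinase gene of striated muscle, and in the apelin receptor gene Aplnr. Mylk4 stood at 9.45 ± 12.8 TPM against 93.5 ± 12.4 TPM in Con, a log2 fold change of -3.74 (SE 0.47, limma adjusted p = 4.35e-09, lower in 7 of 7). Without CAC replicate 3, at 37.9 TPM, its CAC mean was 4.70 TPM. Aplnr stood at 3.87 ± 4.66 against 25.2 ± 7.50 TPM, and its ligand gene Apln at 0.708 ± 0.893 against 8.84 ± 2.08 TPM, with CAC means of 2.19 and 0.374 TPM without the same library. Skeletal actin Acta1 fell by 2.67, Retnla by 2.62 and Plekhh1 by 2.13 on the log2 scale.

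In CAC against Con at week 8, 20 of 21 measured genes of the IL-6, STAT3 and acute-phase list rose and 0 fell (20 and 0 adjusted over the list alone), with a median log2 fold change of 1.87. That list gave camera adjusted p = 2.54e-18, and adjusted p = 0.144 with an estimated correlation. The oncostatin M receptor gene Osmr rose from 2.80 ± 0.337 to 22.1 ± 6.62 TPM, Socs3, a feedback inhibitor of STAT3 signalling, from 2.57 ± 0.550 to 63.0 ± 31.5 TPM, and Il1r1 by 1.51 on the log2 scale. Of 16 macrophage and monocyte markers 14 rose and 0 fell (14 and 1 adjusted over the list alone), with camera adjusted p = 2.19e-08 and adjusted p = 0.443 with an estimated correlation. Among them the scavenger receptor genes Mrc1 and Cd163 rose by 2.25 and 2.54, F13a1 by 2.35 and the complement gene C1qc by 1.69. All 6 measured neutrophil markers rose (6 adjusted over the list alone), with camera adjusted p = 0.00294 and adjusted p = 0.664 with an estimated correlation. Retnlg rose by 1.42, Wfdc21 by 0.86, Csf3r by 0.82 and Cxcr2 by 0.65. B and plasma cell markers went the other way, with 4 of 7 lower, 0 higher and 3 not called (6 lower adjusted over the list alone). They gave camera adjusted p = 6.29e-05, and adjusted p = 0.367 with an estimated correlation, and in the rescaled refit the list missed the threshold at camera adjusted p = 0.0557. The light chain gene Igkc fell by 0.99 on the log2 scale (limma adjusted p = 0.00487). The calls of Cd79a (-0.56), Ighd (-0.49) and Ighm (-0.59) were each lost on leaving out Con replicate 1, up to limma adjusted p = 0.0712, 0.197 and 0.151. That of Ighd was also lost without CAC replicate 7, and that of Ighm without CAC replicates 1, 2, 4, 6 or 7 or Con replicates 2, 3 or 5.

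At week 8, 15 of 21 glucocorticoid targets rose in CAC against Con and 1 fell (16 and 1 adjusted over the list alone), with camera adjusted p = 2.11e-05 and adjusted p = 0.765 with an estimated correlation. The co-chaperone gene Fkbp5 rose from 4.00 ± 1.57 to 36.1 ± 17.9 TPM (limma adjusted p = 6.77e-06), Mt1 by 3.75 and Cebpd by 3.22 on the log2 scale. The list also holds Lcn2, Mt1 and Mt2, which respond to inflammation and metals as well. Of 40 ribosomal protein genes 39 rose and 0 fell (39 and 0 adjusted over the list alone) by a median of 0.64, among them Rpl3 by 1.05, Rps20 by 0.83, Rps16 by 0.79 and Rpl38 by 0.77. They gave camera adjusted p = 1.25e-15, and adjusted p = 0.685 with an estimated correlation. Of 19 immediate early genes 14 rose and 0 fell (14 and 0 adjusted over the list alone), with camera adjusted p = 0.00276 and adjusted p = 0.913 with an estimated correlation. Junb rose by 2.36, Btg2 by 2.18, Myc by 2.12 and Zfp36 by 1.50, and 10 members rose and 1 fell in the rescaled refit. Of 28 targets of ER stress and the transcription factor ATF4, 17 rose and 0 fell (18 and 0 adjusted over the list alone), with camera adjusted p = 0.00723 and adjusted p = 0.964 with an estimated correlation. The amino acid transporter subunit gene Slc3a2 rose by 1.57, Nupr1 by 0.91, Psat1 by 0.76 and Asns by 0.71.

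Contractile and metabolic genes of the heart muscle were mixed at week 8. Cardiac actin Actc1 stood at 4053 ± 2204 TPM in CAC and 9863 ± 892 TPM in Con, a log2 fold change of -1.46 (SE 0.32, limma adjusted p = 2.70e-04), and muscle creatine kinase Ckm fell by 0.69. Cardiac troponin T Tnnt2 rose from 2646 ± 321 to 4358 ± 448 TPM (limma adjusted p = 0.00792). Pdlim5 had a log2 fold change of 0.71 (limma adjusted p = 0.0455), a call lost on leaving out any Con library or any CAC library but replicate 3, up to 0.0967. Of 21 adult sarcomere genes these 2 rose and 2 fell (1 and 2 adjusted over the list alone), with camera adjusted p = 0.00105, direction down, and adjusted p = 0.973 with an estimated correlation. The rescaled refit had 2 rise and 15 fall. Of 32 genes of fatty acid oxidation and PPAR targets 4 rose and 2 fell (3 and 1 adjusted over the list alone), and 4 rose and 23 fell in the rescaled refit. That list gave camera adjusted p = 4.38e-04, direction down, and adjusted p = 0.973 with an estimated correlation. The uncoupling protein gene Ucp3 fell by 1.57 while Ucp2 rose by 1.06, the lipid droplet gene Plin2 by 1.03 and the fatty acid carrier gene Cd36 by 0.46. Of 43 nuclear genes of the respiratory chain 2 were higher and 0 lower (0 and 0 adjusted over the list alone), and 0 were higher and 26 lower in the rescaled refit. The test pointed down (camera adjusted p = 0.0188, adjusted p = 0.998 with an estimated correlation) although the median, 0.03, and the mean, 0.02, were positive. The median of all genes in this comparison was 0.19, so the list lay below the other genes. The 2 called members were Cox6c at 0.35 (limma adjusted p = 0.0314) and Ndufa2 at 0.27 (limma adjusted p = 0.0263). Both calls were lost without CAC replicates 2 or 5 or Con replicates 1, 3 or 5, up to 0.0783 and 0.0941, and that of Cox6c also without Con replicate 4. Of 13 mitochondrially encoded genes 6 fell and 0 rose (6 and 0 adjusted over the list alone), and 12 fell in the rescaled refit, with camera adjusted p = 4.20e-06 and adjusted p = 0.629 with an estimated correlation. The complex I gene mt-Nd1 fell by 0.36 (limma adjusted p = 1.43e-04), mt-Nd4l by 0.26 and mt-Co2 by 0.20. The fall of mt-Nd2 by 0.23 was lost without Con replicate 1 or 3, up to limma adjusted p = 0.0513. Mitochondrially encoded transcripts held 52.2 ± 1.92% of TPM in CAC (SD, n = 7) and 58.3 ± 3.28% in Con (SD, n = 5).

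Genes used as signs of cardiac stress rose in part. Nppb, which encodes the hormone BNP, rose from 154 ± 61.8 to 541 ± 197 TPM, a log2 fold change of 1.80 (limma adjusted p = 8.91e-05, higher in 7 of 7), and the stress-responsive gene Ankrd1 from 944 ± 275 to 7061 ± 2704 TPM. Mybpc2, a myosin binding protein gene of fast skeletal muscle, rose by 2.69, and Actn1 by 1.01. Nppa, which encodes ANP, stood at 934 ± 460 against 187 ± 64.4 TPM (limma adjusted p = 0.0439). That call was lost without any Con library or without CAC replicates 1, 2, 4, 6 or 7, up to 0.0959, and in the rescaled refit (0.0677). The slow myosin gene Myh7 rose by 0.50 (limma adjusted p = 0.0176), a call lost without CAC replicate 2 or Con replicate 1, up to 0.0714. The fast myosin gene Myh6 stood at 4462 ± 798 TPM in CAC and 6762 ± 935 TPM in Con and was not called (limma adjusted p = 0.0566). In the rescaled refit its log2 fold change of -0.82 passed the threshold (limma adjusted p = 4.47e-09). Of 15 genes of the cardiac stress list 7 rose and 1 fell (7 and 1 adjusted over the list alone), and the list as a whole was not called (camera adjusted p = 0.53). Of 24 atrophy ligases and related genes 8 rose and 0 fell (8 and 0 adjusted over the list alone), without a call for the list (camera adjusted p = 0.204). The genes that rose included Mt1, Mt2, the translation inhibitor gene Eif4ebp1 by 1.24 and Fbxo31 by 1.61. The muscle ubiquitin ligase genes Fbxo32 and Trim63 were not called, at 0.17 (limma adjusted p = 0.683) and 0.39 (limma adjusted p = 0.309). Of 30 matrix and fibrosis genes 7 rose and 2 fell (7 and 2 adjusted over the list alone), with a median of -0.07, a mean of 0.28 and a test that pointed down without a call (camera adjusted p = 0.341). The protease gene Mmp3 rose from 0.962 ± 0.514 to 39.7 ± 15.6 TPM, Timp1 by 2.06, Thbs4 by 1.83 and Dcn by 1.31. The collagen genes Col1a1, at -0.17 (limma adjusted p = 0.664), and Col3a1, at -0.04 (limma adjusted p = 0.951), were not called.

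Among 36 interferon response genes 5 rose and 6 fell in CAC against Con at week 8 (5 and 6 adjusted over the list alone), with camera adjusted p = 5.38e-04, direction down, and adjusted p = 0.973 with an estimated correlation. The list was not called in the rescaled refit (camera adjusted p = 0.149). Ifi27l2a rose by 2.13, while the guanylate binding protein genes Gbp3, Gbp4 and Gbp5 fell by 1.07, 0.97 and 0.53. The Gbp genes belong to a family of similar copies, so single values are uncertain. Of 20 clock genes 2 rose and 1 fell, and 0 were called adjusted over the list alone, by limma, where 6 had an unadjusted p below 0.05. The list was not called (camera adjusted p = 0.295), its median, 0.23, and mean, 0.17, were positive and its test pointed down. Per1 at 1.14 lost its call without Con replicate 2 (limma adjusted p = 0.0723), Nr1d1 at -1.33 without CAC replicate 5 (limma adjusted p = 0.0973), and Per2 at 1.17 without CAC replicates 4 or 6 or Con replicates 1 or 2, up to 0.128. Dbp at -0.30 (limma adjusted p = 0.596) and Arntl at -0.57 (limma adjusted p = 0.365) were not called. Neither was Pdk4, a brake on glucose oxidation, at 95.2 ± 21.9 against 176 ± 96.2 TPM (limma adjusted p = 0.22, and 0.046 in the rescaled refit). Angptl4, a lipase inhibitor gene, was called at -0.85 (limma adjusted p = 0.0492). That call was lost without CAC replicates 1, 2, 5, 6 or 7 or Con replicates 1, 2 or 3, up to 0.19.

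Over all genes, limma with Benjamini-Hochberg adjustment called 3834 genes higher and 540 lower in CAC than in Con at week 8. The median log2 difference of all genes was 0.19 as deposited, and the rescaled refit, with a median of 0.01, called 3391 higher and 3106 lower. Of the 4374 calls, 3712 were also called in the same direction in the refit. CAC replicate 3 stood nearer to the Con libraries than the other 6, with 54.9 TPM of Serpina3n against 1665 to 2841 TPM.

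**Figure D1:**
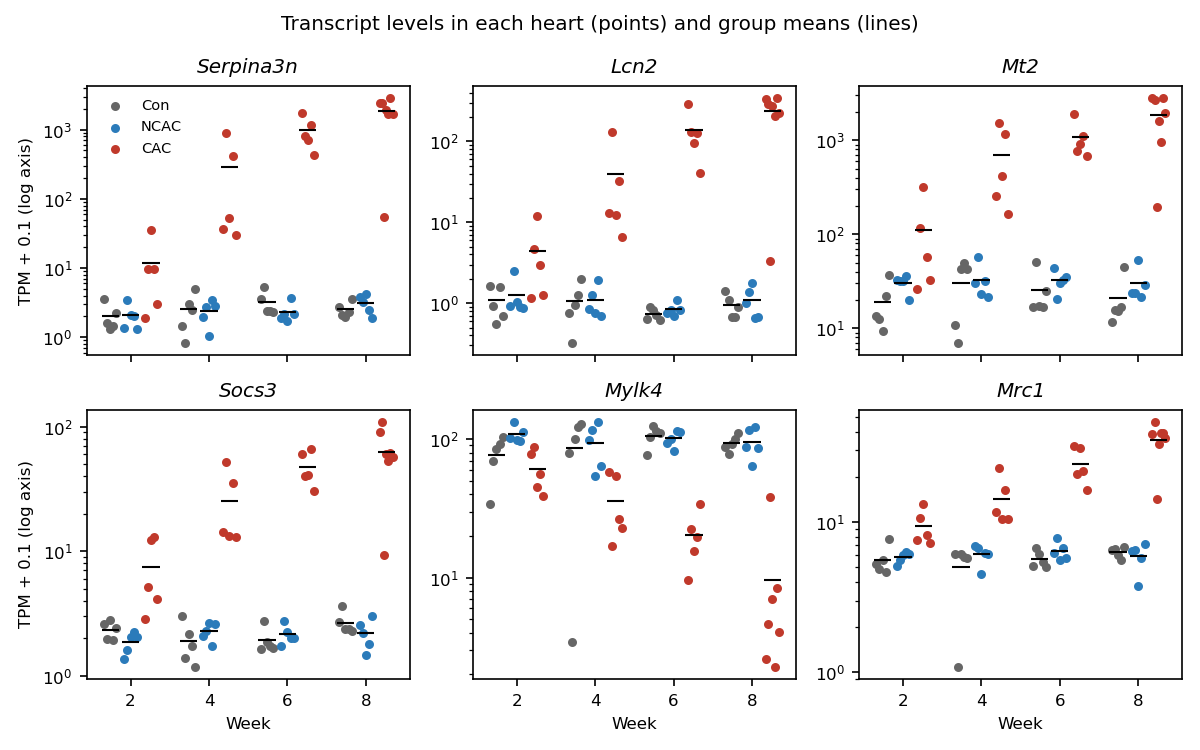
TPM plus 0.1 of 6 genes in each of the 62 libraries (points, log axis) by week and arm, with horizontal lines at group means. Serpina3n in CAC ranges up to 2841 TPM at week 8, where 1 CAC library lies at 54.9 TPM.

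The comparison of CAC with NCAC at week 8 sets cachectic against other melanoma cells. Serpina3n stood at 3.04 ± 0.974 TPM in NCAC (SD, n = 5), a log2 fold change of 8.32 in CAC (SE 0.61, limma adjusted p = 2.64e-16). Lcn2 stood at 1.00 ± 0.481 TPM in NCAC, a log2 fold change of 6.27 in CAC. Ccl8 rose by 5.81, Mt2 by 5.61, Saa3 by 4.82 and Serpina3i by 4.73. Mylk4 fell by 3.73, Acta1 by 2.87, the skeletal calsequestrin gene Casq1 by 2.34, Apln by 2.31, Aplnr by 2.15 and Plekhh1 by 2.14. Of the IL-6, STAT3 and acute-phase list, 20 of 21 genes rose and 0 fell (21 and 0 adjusted over the list alone), with a median of 2.09, camera adjusted p = 6.86e-17 and adjusted p = 0.182 with an estimated correlation. Socs3 rose by 4.13, Osmr by 2.72 and Il1r1 by 1.61. Of 16 macrophage markers 15 rose and 0 fell (15 and 0 adjusted over the list alone), with camera adjusted p = 1.49e-10 and adjusted p = 0.367 with an estimated correlation. Cd163 rose by 2.65, Mrc1 by 2.36, C1qc by 2.07 and the Fc receptor gene Fcgr1 by 1.54. Of 40 ribosomal protein genes 37 rose and 0 fell (38 and 0 adjusted over the list alone), and 28 rose and 1 fell in the rescaled refit, with camera adjusted p = 4.88e-05 and adjusted p = 0.973 with an estimated correlation. Rpl3 rose by 0.99, Rpl10 by 0.75, Rps16 by 0.60 and Rps20 by 0.54.

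Among 21 sarcomere genes 4 fell and 0 rose in CAC against NCAC at week 8 (3 and 0 adjusted over the list alone), and 17 fell and 2 rose in the rescaled refit, with camera adjusted p = 9.79e-06 and adjusted p = 0.888 with an estimated correlation. Actc1 fell by 1.10, Ckm by 0.77 and Myl2 by 0.51. The fall of Mybpc3 by 0.54 (limma adjusted p = 0.0455) was lost without any NCAC library or any CAC library but replicate 3, up to 0.0837. Of 32 fatty acid oxidation genes 4 rose and 2 fell (3 and 1 adjusted over the list alone), and 4 rose and 23 fell in the rescaled refit, with camera adjusted p = 1.15e-05, direction down, and adjusted p = 0.956 with an estimated correlation. Ucp2 rose by 1.30, Plin2 by 1.19 and Cd36 by 0.47, and Ucp3 fell by 1.36. Of 43 respiratory chain genes 0 were called by limma (0 adjusted over the list alone, 1 at an unadjusted p below 0.05) and 42 fell in the rescaled refit. That list gave camera adjusted p = 1.64e-07, direction down, and adjusted p = 0.964 with an estimated correlation. Members with the smallest p were Uqcrfs1, at 606 ± 60.1 against 804 ± 30.4 TPM (limma adjusted p = 0.0754), Atp5d, Ndufa5 and Ndufb10. Of 13 mitochondrially encoded genes 4 fell and 0 rose (4 and 0 adjusted over the list alone), and 13 fell in the refit, with camera adjusted p = 2.31e-07 and adjusted p = 0.501 with an estimated correlation. They were mt-Nd1, by 0.39, mt-Nd3, by 0.32, mt-Nd2, by 0.24, and mt-Co2, by 0.20, and mitochondrially encoded transcripts held 57.2 ± 1.06% of TPM in NCAC (SD, n = 5). Of 7 B and plasma cell markers 5 fell and 0 rose (5 and 0 adjusted over the list alone), with camera adjusted p = 2.33e-06 and adjusted p = 0.287 with an estimated correlation. Igkc fell by 1.02, Cd79a by 0.68, Ighd by 0.59 and Cd79b by 0.49, and the fall of Iglc2 by 0.54 was lost without NCAC replicate 1 (limma adjusted p = 0.0706). Of 36 interferon genes 12 rose and 1 fell (12 and 1 adjusted over the list alone), without a call for the list (camera adjusted p = 0.863). Ifi27l2a rose by 2.47, Irf9 by 0.96, Stat2 by 0.93 and Zbp1 by 0.66.

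Of the genes named against Con, Nppb rose by 1.34 in CAC against NCAC at week 8 (limma adjusted p = 0.00263) and Fkbp5 by 2.64 (limma adjusted p = 7.50e-06). Myh7 at 0.43 (limma adjusted p = 0.0361) lost its call without CAC replicates 1, 2, 4 or 7 or NCAC replicates 1, 2, 4 or 5, up to 0.1, and in the rescaled refit (0.16). Nppa, at 934 ± 460 against 326 ± 211 TPM, was not called (limma adjusted p = 0.0852), nor was Myh6 at -0.59 (limma adjusted p = 0.0575), which was called in the refit (1.50e-09). Pdk4 at 95.2 ± 21.9 against 189 ± 38.2 TPM (limma adjusted p = 0.0615) and Angptl4 at -0.70 (limma adjusted p = 0.0949) were not called in the reported fit. In the refit they were called, at limma adjusted p = 0.00545 and 0.042. Fbxo32 at 0.16, Trim63 at 0.33, Col1a1 at 0.40, Col3a1 at 0.66, Dbp at -0.57 and Arntl at -0.17 were not called, with limma adjusted p from 0.151 to 0.801. In all, limma called 4789 genes higher and 448 lower. The median of all genes was 0.24 as deposited and 0.02 in the rescaled refit, which called 3447 higher and 3048 lower, and of 5237 calls 3836 were called in the same direction in both.

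**Figure D2:**
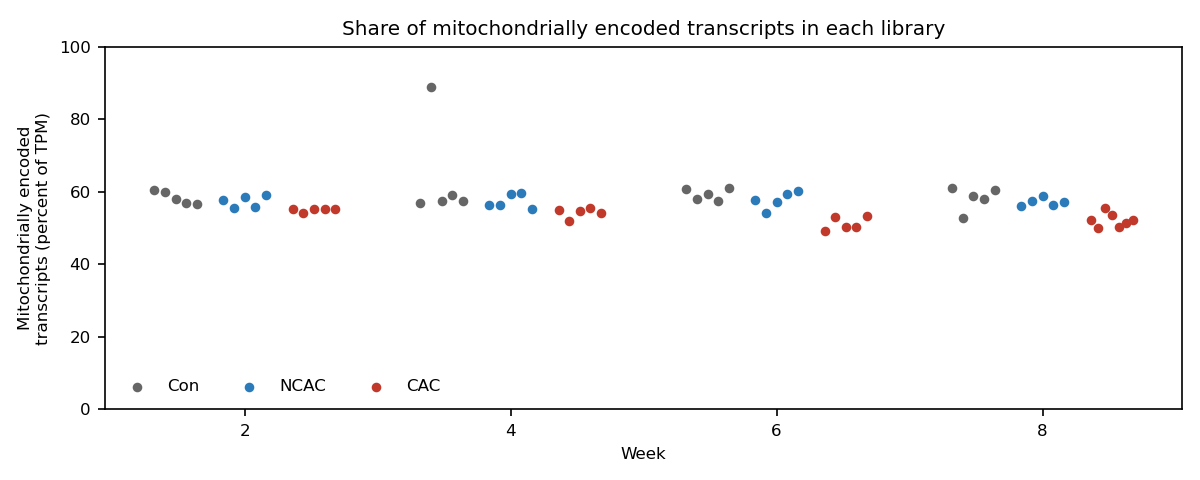
Share of TPM held by mitochondrially encoded transcripts in each library, in percent, by week and arm. CAC means were 51.2% at week 6 and 52.2% at week 8, and Con week 4 replicate 2 stood at 89.1%.

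At week 6 the acute-phase genes already stood far apart. Serpina3n stood at 973 ± 516 TPM in CAC against 3.11 ± 1.31 TPM in Con (SD, n = 5 each), a log2 fold change of 7.78 (SE 0.66, limma adjusted p = 1.08e-13, higher in 5 of 5), and Lcn2 at 137 ± 93.9 against 0.636 ± 0.119 TPM. Mt2 rose by 5.39, Ccl8 by 4.74, Serpina3i by 4.06 and Socs3 by 4.06. Mylk4 fell from 106 ± 17.8 to 20.2 ± 8.99 TPM (limma adjusted p = 2.06e-04), and Kcnip2, a subunit of the transient outward potassium channel, from 92.4 ± 7.43 to 29.1 ± 8.90 TPM. Aplnr fell by 2.28, Apln by 2.18, Retnla by 1.79 and Nrep by 1.77. Of 21 IL-6, STAT3 and acute-phase genes 20 rose and 0 fell (20 and 0 adjusted over the list alone), with a median of 2.07, camera adjusted p = 1.06e-20 and adjusted p = 0.0991 with an estimated correlation. Osmr rose by 2.42 and Il1r1 by 1.44. Of 16 macrophage markers 15 rose and 0 fell (15 and 0 adjusted over the list alone), with camera adjusted p = 1.23e-09 and adjusted p = 0.367 with an estimated correlation. Cd163 rose by 2.04, F13a1 by 1.94, Mrc1 by 1.92 and C1qc by 1.72. Of 40 ribosomal protein genes 38 rose and 0 fell (39 and 0 adjusted over the list alone), with camera adjusted p = 9.95e-13 and adjusted p = 0.765 with an estimated correlation. Rpl3 rose by 0.91 and Rps16 and Rps20 each by 0.67. Of 15 cell cycle genes 7 fell and 1 rose (8 and 1 adjusted over the list alone), with camera adjusted p = 5.45e-07 and adjusted p = 0.515 with an estimated correlation. The proliferation marker gene Mki67 fell by 0.70, Cdk1 by 0.57 and Rrm2 by 0.51, and Mcm4 rose by 0.41, a call lost without CAC replicate 1 (limma adjusted p = 0.0517). Of 13 mitochondrially encoded genes 6 fell and 0 rose (7 and 0 adjusted over the list alone), with camera adjusted p = 2.13e-12 and adjusted p = 0.274 with an estimated correlation. The genes mt-Nd2, mt-Nd3, mt-Nd1 and mt-Co2 fell by 0.41, 0.39, 0.39 and 0.27, and these transcripts held 51.2 ± 1.77% of TPM in CAC and 59.3 ± 1.59% in Con (SD, n = 5). Of 32 fatty acid oxidation genes 5 rose and 1 fell (4 and 1 adjusted over the list alone), 3 rose and 15 fell in the rescaled refit, and the test pointed down (camera adjusted p = 0.00245, adjusted p = 0.973 with an estimated correlation). Plin2 rose by 1.16 and Ucp2 by 0.72. The rise of Cpt1a by 0.66 was lost without CAC replicate 4 (limma adjusted p = 0.111).

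Against NCAC at week 6 Serpina3n rose by 8.11 from 2.22 ± 0.763 TPM (SE 0.66, limma adjusted p = 4.98e-14), Lcn2 by 6.05, Mt2 by 4.95, Ccl8 by 4.85, Serpina3i by 3.95 and Socs3 by 3.94. Aplnr fell by 2.60, Retnla by 2.40, Apln by 2.38, Mylk4 by 2.37 and Casq1 by 2.32. Of 21 IL-6, STAT3 and acute-phase genes 20 rose and 0 fell (20 and 0 adjusted over the list alone), with camera adjusted p = 1.96e-20 and adjusted p = 0.0991 with an estimated correlation. Osmr rose by 2.44 and Il1r1 by 1.36. Of 16 macrophage markers 14 rose and 0 fell (14 and 0 adjusted over the list alone), with camera adjusted p = 6.59e-08 and adjusted p = 0.496 with an estimated correlation. Cd163 rose by 2.02, F13a1 by 1.85, Mrc1 by 1.76 and Fcgr1 by 1.21. Of 40 ribosomal protein genes 37 rose and 0 fell (38 and 0 adjusted over the list alone), with camera adjusted p = 1.49e-10 and adjusted p = 0.813 with an estimated correlation. Rpl3 rose by 0.97, Rpl10 by 0.80, Rps16 by 0.59 and Rps20 by 0.56. Of 7 erythroid markers 5 fell and 0 rose (6 and 0 adjusted over the list alone), with camera adjusted p = 3.40e-06 and adjusted p = 0.367 with an estimated correlation. The haemoglobin genes Hbb-bt, Hbb-bs and Hba-a1, copies whose reads can be shared, fell by 2.05, 2.04 and 1.79. NCAC replicate 2 held 18553 TPM of haemoglobin transcripts. Without it the calls of Hbb-bs (limma adjusted p = 0.0546), Hbb-bt, Hba-a1 and Alas2 (-1.68) were lost. The call of Hbb-bt was also lost without CAC or NCAC replicate 1, that of Alas2 without CAC replicates 1 or 4, and that of Hba-a1 without CAC replicates 1 or 4 or NCAC replicate 1. The highest limma adjusted p of these 3 were 0.0873, 0.097 and 0.134. Over all genes limma called 3008 higher and 307 lower against Con, and 2889 higher and 385 lower against NCAC. The median of all genes was 0.21 and 0.19 as deposited, and the rescaled refit called 2466 higher and 2241 lower against Con, and 2640 higher and 2472 lower against NCAC.

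**Figure D3:**
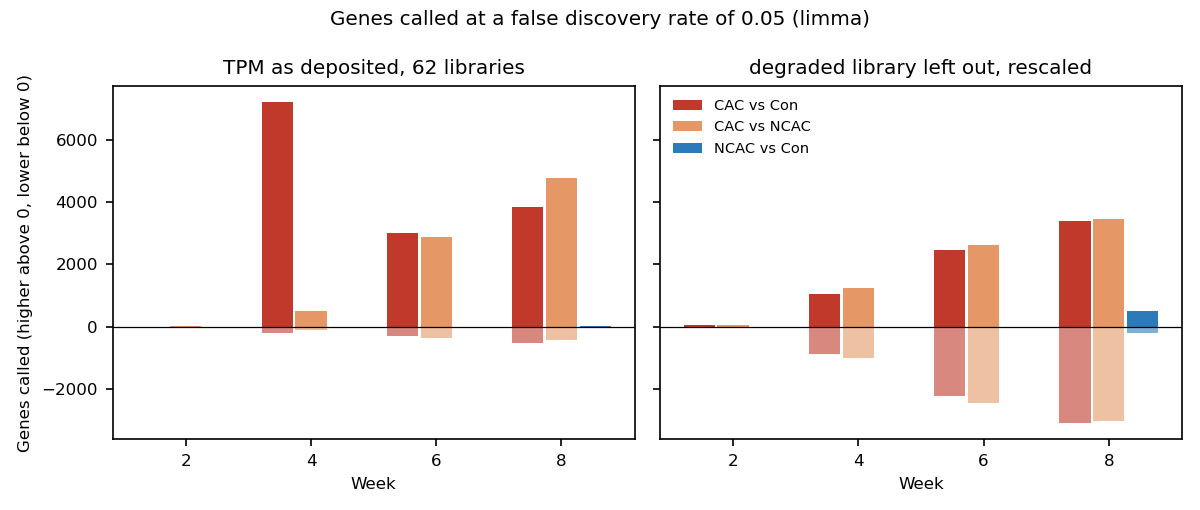
Number of genes called higher (up) and lower (down) in each pairwise comparison by week, with all libraries as deposited and in the rescaled refit. Against Con at week 8 the split was 3834 higher and 540 lower as deposited, and 3391 higher and 3106 lower in the refit.

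At week 4 Serpina3n stood at 286 ± 377 TPM in CAC and 2.46 ± 1.63 TPM in Con (SD, n = 5 each), a log2 fold change of 5.22 (SE 0.66, limma adjusted p = 8.48e-08, higher in 5 of 5). Without the degraded Con library it was called at 1.85e-06. CAC replicate 2 stood at 892 TPM, and without it the CAC mean was 134 TPM. Mt2 rose by 4.35, Ccl8 by 3.73, Lcn2 by 3.60, Socs3 by 3.04 and Mt1 by 2.46. Apln fell by 1.90, Aplnr by 1.69, the prion-like gene Prnd by 1.53, the imprinted gene Mest by 1.23, Rtn4r by 1.16 and the intermediate filament gene Nes by 1.15. Of 21 IL-6, STAT3 and acute-phase genes 19 rose and 0 fell (20 and 0 adjusted over the list alone), with camera adjusted p = 1.79e-09 and adjusted p = 0.406 with an estimated correlation. Junb rose by 2.41 and Osmr by 1.73, and 14 members rose in the rescaled refit. Among 16 macrophage markers 15 rose and 0 fell (15 and 0 adjusted over the list alone), 8 in the rescaled refit, with camera adjusted p = 2.10e-05 and adjusted p = 0.719 with an estimated correlation. Mrc1 rose by 1.44, C1qc by 1.32, Csf1r by 1.12 and Fcgr1 by 1.06. The fold changes against Con at this week include the degraded library. It moved the median of all genes from 0.09 to 0.37, so rises of most genes are overstated by it. Of 15 cell cycle genes 8 fell and 2 rose (8 and 2 adjusted over the list alone), with camera adjusted p = 7.84e-18 and adjusted p = 0.0991 with an estimated correlation. Mki67 fell by 0.73, Cdc20 by 0.52 and Rrm2 by 0.49, and the rise of Mcm4 by 0.45 was lost without the degraded library (limma adjusted p = 0.0723). Of 444 list tests 172 were called, and 4 of them held with an estimated correlation, all in comparisons with Con at week 4. Of 13 mitochondrially encoded genes 7 fell and 0 rose in CAC (9 and 0 adjusted over the list alone), with camera adjusted p = 3.72e-26 and adjusted p = 0.0226 with an estimated correlation. They were led by mt-Nd2 at -0.31, mt-Co1 at -0.22, mt-Co2 at -0.26 and mt-Nd1 at -0.29, and 1 fell in the rescaled refit. The call of mt-Nd1 was lost without the degraded library (limma adjusted p = 0.0734). Of 14 endothelial markers 2 fell and 1 rose (2 and 1 adjusted over the list alone), with camera adjusted p = 9.95e-13 and adjusted p = 0.0226 with an estimated correlation. The cadherin gene Cdh5 fell by 0.44 and Vwf rose by 0.69, and the fall of the VEGF receptor gene Kdr by 0.49 was lost without CAC replicates 2 or 4 or Con replicate 1, up to limma adjusted p = 0.0652. The degraded library holds 89.1% mitochondrial TPM. In the rescaled refit, which leaves it out and also rescales, 0 of the list calls held with an estimated correlation. Which of these changes removed the calls was not tested. Limma called 7225 genes higher and 199 lower against Con, and 1587 higher and 296 lower without the degraded library. The median of all genes was 0.37 with it and 0.09 without it. The rescaled refit called 1058 higher and 873 lower, 905 genes in all without CAC replicate 2 and 1271 without Con replicate 5.

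The comparison with NCAC at week 4 does not use the degraded library's own values, but the spread which that library widens enters its p-values. Serpina3n rose there by 5.22 from 2.30 ± 0.942 TPM (SE 0.66, limma adjusted p = 1.74e-07). Mt2 rose by 3.98, Lcn2 by 3.55, Ccl8 by 3.36, Socs3 by 2.83 and the acute-phase gene Itih4 by 2.36. Apln fell by 2.02, Prnd by 1.56 and the interferon-induced GTPase gene Tgtp1 by 1.33. The falls of Aplnr (-1.65), Casq1 (-1.45) and Tgtp2 (-1.34), a near copy of Tgtp1, were lost on leaving out 1 library, up to limma adjusted p = 0.209, 0.1 and 0.109. For Aplnr these were CAC replicates 2 and 4 and NCAC replicates 1, 3 and 5, for Casq1 CAC replicate 2 and NCAC replicates 1 and 2, and for Tgtp2 CAC replicates 3 and 4 and NCAC replicates 2 and 4. In the IL-6, STAT3 and acute-phase list 13 of 21 genes rose and 0 fell (18 and 0 adjusted over the list alone), with camera adjusted p = 2.41e-21 and adjusted p = 0.0991 with an estimated correlation. Junb rose by 1.94 and Osmr by 1.68. Among 16 macrophage markers 9 rose and 0 fell (15 and 0 adjusted over the list alone), with camera adjusted p = 1.98e-11 and adjusted p = 0.362 with an estimated correlation. Mrc1 rose by 1.06, C1qc by 0.98, Csf1r by 0.80, and Fcgr1 by 0.73, a call lost without CAC replicate 4 (limma adjusted p = 0.0539). Of 15 cell cycle genes 4 fell and 0 rose (11 and 0 adjusted over the list alone), with camera adjusted p = 1.01e-11 and adjusted p = 0.287 with an estimated correlation. The falls of Mki67 (-0.78), Rrm2 (-0.55), Mcm5 (-0.53) and Top2a (-0.53) were each lost without NCAC replicate 2, up to limma adjusted p = 0.0656, 0.0597, 0.128 and 0.173. Those of Mki67, Mcm5 and Top2a were also lost without CAC replicate 2, those of Mcm5 and Top2a without CAC replicates 1 or 4 or NCAC replicates 1 or 5, and that of Top2a without CAC replicate 3 or NCAC replicate 4. Of 36 interferon genes 4 fell and 0 rose (6 and 0 adjusted over the list alone), with camera adjusted p = 1.81e-10 and adjusted p = 0.719 with an estimated correlation. Gbp3 fell by 1.12 and Gbp4 by 1.00, while Gbp5 (-0.59) lost its call without CAC replicate 2 (limma adjusted p = 0.0608) and Gbp7 (-0.65) without CAC replicates 3 or 4 or NCAC replicates 1 or 4, up to 0.0969. Limma called 506 genes higher and 115 lower, 290 in all without CAC replicate 2 and 2074 in all without the degraded library. The rescaled refit called 1247 higher and 1008 lower, 1198 in all without CAC replicate 2.

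At week 2, the earliest time, Serpina3n stood at 11.8 ± 13.4 TPM in CAC, 1.95 ± 0.937 TPM in Con and 1.96 ± 0.879 TPM in NCAC, and Mt2 at 110 ± 121, 18.8 ± 11.2 and 30.2 ± 6.13 TPM (SD, n = 5 each), neither called. Without CAC replicate 3 the CAC means were 5.99 and 58.1 TPM. Against NCAC the Wnt antagonist gene Sfrp1 stood at 8.97 ± 2.21 TPM in CAC and 4.03 ± 0.809 TPM in NCAC (SD, n = 5 each), a log2 fold change of 0.97 (SE 0.16, limma adjusted p = 0.00201, higher in 5 of 5). The cytokine receptor kinase gene Jak3 rose by 0.81 (limma adjusted p = 0.0367), a call lost without CAC replicates 2 or 3 or NCAC replicates 2, 3, 4 or 5, up to 0.354. Of 21 IL-6, STAT3 and acute-phase genes 0 were called by limma over all genes, 9 had an unadjusted p below 0.05, and 7 rose and 0 fell adjusted over the list alone. That list gave camera adjusted p = 1.17e-07, with a median of 0.51, and adjusted p = 0.524 with an estimated correlation. Socs3 stood at 7.38 ± 4.76 against 1.76 ± 0.363 TPM (limma adjusted p = 0.102), Il1r1 at 5.40 ± 1.02 against 3.11 ± 0.202 TPM (limma adjusted p = 0.0557), and Osmr and Pim1 at log2 differences of 0.80 and 0.87. Of 16 macrophage markers 0 were called by limma (0 adjusted over the list alone, 4 at an unadjusted p below 0.05), with camera adjusted p = 0.0111 and adjusted p = 0.973 with an estimated correlation. Mrc1 stood at 0.58, Lyz2 at 0.45, Cd14 at 0.43 and Ccr2 at 0.39. Of 36 interferon genes 0 were called by limma (0 adjusted over the list alone, 8 at an unadjusted p below 0.05), with a median of -0.28, camera adjusted p = 1.15e-19 and adjusted p = 0.367 with an estimated correlation. The class I gene H2-D1 stood at 57.7 ± 17.5 against 131 ± 67.0 TPM, Gbp3 at -0.83, Psmb9 at -0.50 and Gbp5 at -0.40, none called. Limma called these 2 genes, with 683 at an unadjusted p below 0.05, and limma's voom on the recovered reads called 13. Without the degraded library limma called 74, and with array quality weights 1379. The count was 14 without CAC replicate 1 and 1 without CAC replicate 2 or NCAC replicates 2, 3 or 5. The rescaled refit called 93, 64 higher and 29 lower, with 144 without CAC replicate 2, 23 without replicate 3, 25 without replicate 4 and 50 without replicate 5. Without NCAC replicates 1, 3 and 5 the refit called 31, 45 and 27.

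Against Con at week 2, limma called 0 genes, with 458 at an unadjusted p below 0.05, and voom called 13. Without the degraded library limma called 231, and with array quality weights 1110. Stat3 itself stood at 40.3 ± 4.32 TPM in CAC and 24.9 ± 6.30 TPM in Con (SD, n = 5 each; limma adjusted p = 0.565, and 0.00404 in the rescaled refit). Of 21 IL-6, STAT3 and acute-phase genes 0 were called over all genes, 6 had an unadjusted p below 0.05, and 4 rose and 0 fell adjusted over the list alone, with camera adjusted p = 4.51e-07 and adjusted p = 0.604 with an estimated correlation. Socs3 stood at 1.18, Osmr at 0.75 and Il1r1 at 0.37, not called. Of 16 macrophage markers 0 were called over all genes, 6 had an unadjusted p below 0.05, and 4 rose and 0 fell adjusted over the list alone, with camera adjusted p = 1.26e-07 and adjusted p = 0.515 with an estimated correlation. Csf1r stood at 14.5 ± 2.02 against 9.39 ± 1.56 TPM, F13a1 at 0.78, Mrc1 at 0.64 and Fcgr1 at 0.49. Of 36 interferon genes 0 were called by limma (0 adjusted over the list alone, 1 at an unadjusted p below 0.05), with camera adjusted p = 1.33e-19 and adjusted p = 0.367 with an estimated correlation. Gbp3 stood at -0.64, H2-D1 at -0.62, Isg15 at -0.52 and Xaf1 at -0.28. The count rose to 5 without CAC replicate 1 and 1 without CAC replicate 2. The rescaled refit called 50, 44 higher and 6 lower, with 136 without CAC replicate 1, 31 without replicate 2, 18 without replicate 3 and 30 without replicate 4. Without Con replicates 1 and 4 the refit called 28 and 78.

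**Figure D4:**
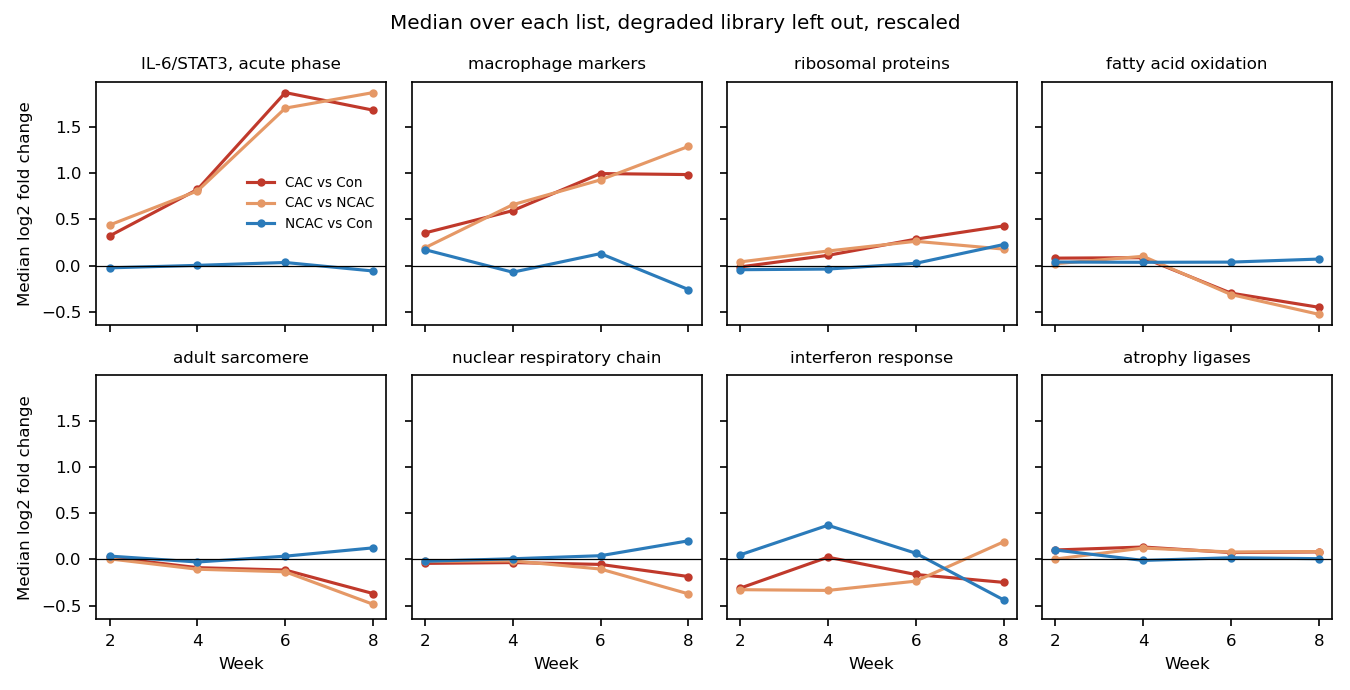
Median log2 fold change in the rescaled refit of the measured members of 8 gene lists by week for CAC against Con, CAC against NCAC and NCAC against Con. The IL-6, STAT3 and acute-phase list stands at 0.32, 0.82, 1.87 and 1.68 against Con at weeks 2, 4, 6 and 8 in this refit.

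NCAC hearts, from animals with melanoma cells that do not cause cachexia, were compared with Con. At week 8 ribosomal protein genes stood slightly higher, with Rps18 at 34.1 ± 2.36 TPM in NCAC and 23.6 ± 2.24 TPM in Con (SD, n = 5 each; limma adjusted p = 0.269). Of the 40 members 0 were called by limma, 11 had an unadjusted p below 0.05, and 2 were higher and 0 lower adjusted over the list alone. The list rose by a median of 0.18 (camera adjusted p = 8.82e-26, adjusted p = 0.367 with an estimated correlation), with Rpl13 at 0.37, Rpl38 at 0.35 and Rps20 at 0.29. Of 43 respiratory chain genes 0 were called by limma (0 adjusted over the list alone, 1 at an unadjusted p below 0.05), with a median of 0.15, camera adjusted p = 1.67e-10 and adjusted p = 0.882 with an estimated correlation. Cox5a stood at 0.29, Ndufa5 and Cox7b each at 0.27 and Ndufa2 at 0.21. Of 36 interferon genes 0 were called over all genes, 17 had an unadjusted p below 0.05, and 13 were lower and 0 higher adjusted over the list alone. That list fell by a median of 0.47 (camera adjusted p = 4.29e-20, adjusted p = 0.367 with an estimated correlation). Irf1 stood at 7.75 ± 0.901 against 11.3 ± 1.43 TPM (limma adjusted p = 0.164, and 0.00834 in the rescaled refit), Xaf1 at -0.51, Stat2 at -0.49 and Ddx58 at -0.36. In the rescaled refit 27 ribosomal and 18 respiratory chain genes rose and 4 interferon genes fell. Limma called 1 gene, the predicted gene Gm2000 at 1.34 (limma adjusted p = 0.0188), chosen after its value was seen, with 689 at an unadjusted p below 0.05, and voom called 211. That call was lost without NCAC replicates 2, 3 or 4 or Con replicates 1, 3 or 4, up to limma adjusted p = 0.159, and 2 genes were called without NCAC replicate 5. The rescaled refit called 711, 490 higher and 221 lower, with 232, 461 and 1200 without NCAC replicates 3, 4 and 5, and 421 and 465 without Con replicates 3 and 5. The balance turned with the scaling, since rescaling all 62 libraries by the median of ratios called 166 higher and 44 lower, and rescaling without mitochondrially encoded and haemoglobin genes 45 higher and 151 lower.

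At weeks 2, 4 and 6 limma called 0 genes between NCAC and Con, with 292, 5721 and 73 at an unadjusted p below 0.05. Voom called 0 in each, and the rescaled refit 3, 0 and 0, where the 3 of week 2 became 11 without NCAC replicate 2, 1 without Con replicate 3 and 0 without NCAC replicates 1, 3 or 4 or Con replicates 1, 2 or 4. At week 4 the count was 0 with the degraded Con library and without it, where 103 genes had an unadjusted p below 0.05. It was 6642, 6420, 4881 and 5337 on leaving out Con replicates 1, 3, 4 and 5, fits that keep the degraded library. Of 13 mitochondrially encoded genes 0 were called by limma at week 4 (0 adjusted over the list alone, 7 at an unadjusted p below 0.05), with camera adjusted p = 1.85e-34, direction down, and adjusted p = 0.00706 with an estimated correlation. The member mt-Nd6 stood at -0.46 and mt-Nd3 at -0.22. Of 14 endothelial markers 0 were called (0 adjusted over the list alone, 0 at an unadjusted p below 0.05), with camera adjusted p = 1.91e-16 and adjusted p = 0.00706 with an estimated correlation. Aqp1 stood at -0.42 and Rgcc at -0.39. In the rescaled refit, which leaves out the degraded library and also rescales, neither list was called (camera adjusted p = 0.494 and 0.0571). Of 36 interferon genes 0 were called by limma at week 4 (0 adjusted over the list alone, 9 at an unadjusted p below 0.05), with a positive median and mean of 0.41 and a test that pointed down without a call (camera adjusted p = 0.986). Gbp7 stood at 0.49, Gbp4 at 0.48, Usp18 at 0.46 and Irf9 at 0.40. These values include the degraded library, with which the median of all genes was 0.276, and 0.01 without it. In the rescaled refit the interferon list rose (camera adjusted p = 1.35e-20, adjusted p = 0.495 with an estimated correlation). At week 2, of 21 glucocorticoid targets 0 were called (0 adjusted over the list alone, 6 at an unadjusted p below 0.05), and the list rose by a median of 0.51 (camera adjusted p = 1.98e-11, adjusted p = 0.367 with an estimated correlation). Tsc22d3 stood at 48.4 ± 9.23 against 24.7 ± 8.05 TPM, Ddit4 at 1.25, Fam107a at 1.00 and Cebpd at 0.98. At week 6, of 7 erythroid markers 0 were called (0 adjusted over the list alone, 2 at an unadjusted p below 0.05), and the list rose by a median of 1.02 (camera adjusted p = 9.16e-09, adjusted p = 0.259 with an estimated correlation). Hba-a1 stood at 1.50, Hbb-bs at 1.26 and Alas2 at 1.02, and haemoglobin held 18553 TPM in NCAC replicate 2.

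The CAC minus Con difference of Serpina3n was 6.96 greater at week 8 than at week 2 on the log2 scale (SE 0.90, limma adjusted p = 2.58e-07), that of Lcn2 5.26, of Ccl8 4.88 and of Saa3 4.76. Those of Mylk4, Retnla, Ucp3 and the albumin gene Alb moved by -3.44, -3.32, -2.94 and -2.27. Limma called 1016 such genes higher and 133 lower, and 1826 in all without CAC week 8 replicate 3. The CAC minus NCAC difference, which uses the same CAC libraries and so is not independent of the other, moved for Serpina3n (6.75), Lcn2 (5.27), Ccl8 (4.96) and Saa3 (4.61), and for Mylk4 (-2.85), Retnla (-2.79), the sodium channel gene Scn4a (-2.30) and the clock gene Nr1d1 (-2.19). There 1569 genes were called higher and 144 lower. The rescaled refit called 2080 higher and 1862 lower against Con, and 2093 higher and 1922 lower against NCAC. Between weeks 8 and 6 limma called 0 genes in the CAC minus Con difference, with 199 at an unadjusted p below 0.05, and voom called 0. The count was 4 without CAC week 8 replicate 3, and the rescaled refit called 26. On leaving out single libraries the refit called 4 to 263, and 19 of the 22 libraries moved it by over 1.5 times, the most without CAC week 8 replicate 3. Of the genes called against Con, 2588 were higher at both week 6 and week 8, where 919.5 would be expected of independent lists, and 259 lower at both, where 13.2 would be expected. Against NCAC the same counts were 2646 (1103 expected) and 246 (13.8 expected). In the rescaled refit 2068 were higher (666.7 expected) and 1843 lower (554.9 expected) at both weeks against Con, and 2107 (725.5 expected) and 1880 (600.7 expected) against NCAC. The Con and NCAC libraries of the 2 weeks were different, so no control was shared. Both weeks were fitted with the same spread per gene, however, so their calls are not independent. The expected numbers are therefore only a reference.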

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

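The limma tests of the comparisons and of the differences between weeks were fixed in advance, and the other tests in this part were chosen after the results were seen. Of 96 groups of values tested for a library far from its group, 16 were singled out, where chance gives about 1 in 20.

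More genes were called higher than lower in CAC at week 8, 87.7% against Con and 91.4% against NCAC. Rescaling without mitochondrially encoded and haemoglobin genes gave 58.9% against Con and 74.6% against NCAC, with medians of all genes of 0.035 and 0.124. The rescaling moved the median against Con from 0.189 to 0.035, so most of that shift went with these transcripts. Whether they are the whole source against Con could not be told. Against NCAC at week 8 a shift of them is excluded as the whole cause. At week 6 the same rescaling moved the share from 90.7% to 49.6% against Con and from 88.2% to 53.2% against NCAC. The medians there were -0.019 and 0.005. At week 8, leaving out 100 abundant nuclear genes as well gave 43.4% and 57%, but brought the median of all genes to -0.039 and 0.03, close to a centring. A balanced split follows from centring, so whether abundant nuclear genes are the source could not be told. A rise of total RNA per heart was not tested, since no spike-in was measured.

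CAC week 8 replicate 3 stood at 54.9 TPM of Serpina3n (others 1665 to 2841) and 3.22 TPM of Lcn2 (209 to 342), with 32860 TPM of haemoglobin (165 to 6607) and a median correlation of 0.983 with other libraries (0.946 to 0.958). An exchange of labels with a Con, NCAC or week 2 CAC library is excluded, since 0 of those 45 reached 1665 TPM of Serpina3n and the highest stood at 34.8. An exchange with a CAC library of week 4 or 6 was not tested. Those libraries stood at 29.8 to 892 and 423 to 1767 TPM of Serpina3n. A week 8 Con or NCAC animal under a wrong label is excluded too, since 60.5% of 688 genes lay beyond all 10 such libraries, against at most 21.7% for any 1 of them. Mixing of cachectic with control RNA could not be told, with a gap of 33.7 points between the share over higher genes (15.7%) and lower genes (49.4%), and NCAC replicate 3 had a gap of 42.8. A weaker disease in this animal was not tested.

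H2-Ea-ps, whose promoter is deleted in C57BL/6 mice, was at or above 1 TPM in 54 of 62 libraries, with a median of 11.2 TPM, which excludes that all animals carried the deletion. A fixed sharing of reads with H2-Aa is excluded, since the ratio of these genes spanned 186.9-fold while H2-Aa spanned 14.1-fold. That span came from libraries under 1 TPM of H2-Ea-ps, and in the other 54 the ratio lay between 0.461 and 1.24. Within that range no library lay between 0.663 and 0.876, so the ratios formed a lower and a higher set. The source of these sets was not tested. The 8 libraries under 1 TPM lay in 6 groups of all 3 arms, and 1 of them was CAC week 8 replicate 3 at 0 TPM, where the other 6 CAC week 8 libraries stood at 3.75 to 40.06 TPM. The T cell genes Cd3e and Cd8a reached at most 0.73 and 0.24 TPM.

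Other libraries far from their group were these. Con week 4 replicate 2 had 89.1% mitochondrial TPM (others 56.8 to 59.2%) and a median correlation of 0.884 (0.985 to 0.990). CAC week 2 replicate 2 had 54.2% mitochondrial TPM (55.2 to 55.4%), and CAC week 4 replicate 5 had 46.4 M reads (45.4 to 45.6). NCAC week 6 replicate 2 had 18550 TPM of haemoglobin (2014 to 6288). Con week 2 replicate 1 and NCAC week 8 replicate 3 had median correlations of 0.979 (0.988 to 0.990) and 0.983 (0.988 to 0.989). Myh6 stood at 7304 TPM in NCAC week 8 replicate 4 (6355 to 6530), Trim63 at 155 TPM in Con week 8 replicate 2 (117 to 124) and Pdk4 at 257 TPM in NCAC week 8 replicate 3 (165 to 175). Mt2 stood at 52.6 TPM in NCAC week 8 replicate 3 (21.6 to 28.5) and 45.3 TPM in Con week 8 replicate 5 (11.6 to 16.8).

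Differences between weeks 8 and 2 that passed the limma test were 1149 for CAC minus Con and 1713 for CAC minus NCAC. Against Con they included Serpina3n (6.96), Lcn2 (5.26), Ccl8 (4.88), Saa3 (4.76), Mylk4 (-3.44), Retnla (-3.32), Ucp3 (-2.94) and Alb (-2.27). Against NCAC they included Serpina3n (6.75), Lcn2 (5.27), Ccl8 (4.96), Saa3 (4.61), Mylk4 (-2.85), Retnla (-2.79), Scn4a (-2.30) and Nr1d1 (-2.19).

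With labels exchanged in up to 100 ways, the real one included, chance was taken as excluded where fewer than 5 ways called as many genes as the real labels, without adjustment over the 19 counts tested. The highest other count stands in brackets. No other way called as many against Con at week 6 with 3315 (1342) and week 8 with 4374 (4235), nor against NCAC at weeks 4, 6 and 8 with 621 (94), 3274 (1844) and 5237 (4841). The same held in the rescaled refit for 50 (36) and 93 (68) at week 2 against Con and NCAC and for 711 (445) for NCAC against Con at week 8, so chance can be excluded there at this bar. It can be excluded only by the share of ways, since a few others called more, for 7424 (7784, 3 ways) at week 4 against Con, 1931 (1947, 2 ways) in its rescaled refit, and the week 8 to week 2 differences with 1149 (1878, 4 ways) and 1713 (2277, 2 ways). Of the 7424 calls 1717 were also made with the degraded library left out and no rescaling. Of the same 7424, the rescaled refit called 1230 in the same direction, 8 in the opposite direction and 6186 not at all. Chance cannot be excluded for 2 (15, 5 ways) against NCAC at week 2. The test decides nothing for a real count of 0, which all 100 ways reach, as against Con at week 2 with 0 (3), for NCAC against Con at weeks 2, 4 and 6 with 0 (1), 0 (8433) and 0 (0), and for the week 8 to week 6 difference with 0 (81). Nor does it for NCAC against Con at week 8 with 1 (0), a single call that was lost without any of 6 libraries. Some other groupings called far more than the real one (8433, 81 and 15). Each of these is the highest of many groupings, so it does not by itself show structure among the samples. At week 4 Con holds the degraded library.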

How the results depend on the processing

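Where a count of calls moved with the processing, the cause was not tested unless the setting itself shows it. The balance of higher and lower calls moved too, for CAC against Con at week 6 from 90.7% higher as reported to 52.4% in the rescaled refit. For NCAC against Con at week 8 it was 79% higher with median-of-ratios rescaling (166 and 44) and 23% rescaled without mitochondrial and haemoglobin genes (45 and 151). The settings without the degraded library and those with voom were chosen after the data were seen, the others before. Counts in brackets name their comparison. With a pseudocount of 0.1 the counts moved to 1 (CAC-Con week 2) and 7 (CAC-NCAC week 2). Without a filter the counts moved to 13 (CAC-Con week 2), 14 (CAC-NCAC week 2), 0 (NCAC-Con week 8) and 1 (CAC-Con weeks 8 to 6). With the stricter filter, which tests fewer genes the counts moved to 3 (CAC-Con week 2), 2149 (CAC-NCAC week 6), 2836 (CAC-Con week 8), 3304 (CAC-NCAC week 8), 659 (CAC-Con weeks 8 to 2) and 968 (CAC-NCAC weeks 8 to 2). With median-of-ratios rescaling the counts moved to 20 (CAC-Con week 2), 23 (CAC-NCAC week 2), 2667 (CAC-Con week 4), 1296 (CAC-NCAC week 4), 210 (NCAC-Con week 8), 2487 (CAC-Con weeks 8 to 2) and 2673 (CAC-NCAC weeks 8 to 2). Rescaled without mitochondrial and haemoglobin genes the counts moved to 15 (CAC-Con week 2), 18 (CAC-NCAC week 2), 2416 (CAC-Con week 4), 1190 (CAC-NCAC week 4), 196 (NCAC-Con week 8), 2365 (CAC-Con weeks 8 to 2) and 3080 (CAC-NCAC weeks 8 to 2). With array quality weights the counts moved to 1110 (CAC-Con week 2), 1379 (CAC-NCAC week 2), 25 (NCAC-Con week 2), 2849 (CAC-Con week 4), 2294 (CAC-NCAC week 4), 7703 (CAC-Con week 6), 7502 (CAC-NCAC week 6), 8642 (CAC-Con week 8), 8685 (CAC-NCAC week 8), 909 (NCAC-Con week 8), 6056 (CAC-Con weeks 8 to 2), 140 (CAC-Con weeks 8 to 6), 6189 (CAC-NCAC weeks 8 to 2) and 6819 (shared by weeks 6 and 8). With the replicate block the counts moved to 1 (CAC-Con week 2) and 1 (CAC-NCAC week 2). With the compared groups fitted alone the counts moved to 22 (CAC-Con week 2), 132 (CAC-NCAC week 2), 77 (CAC-Con week 4), 1657 (CAC-NCAC week 4), 7129 (CAC-Con week 6), 6569 (CAC-NCAC week 6), 6 (NCAC-Con week 8), 2118 (CAC-Con weeks 8 to 2), 3395 (CAC-NCAC weeks 8 to 2) and 4911 (shared by weeks 6 and 8). Without the degraded library the counts moved to 231 (CAC-Con week 2), 74 (CAC-NCAC week 2), 1883 (CAC-Con week 4), 2074 (CAC-NCAC week 4), 6997 (CAC-Con week 6), 6841 (CAC-NCAC week 6), 7619 (CAC-Con week 8), 8295 (CAC-NCAC week 8), 89 (NCAC-Con week 8), 3330 (CAC-Con weeks 8 to 2), 19 (CAC-Con weeks 8 to 6), 4479 (CAC-NCAC weeks 8 to 2) and 5836 (shared by weeks 6 and 8). In the rescaled refit the counts moved to 50 (CAC-Con week 2), 93 (CAC-NCAC week 2), 3 (NCAC-Con week 2), 1931 (CAC-Con week 4), 2255 (CAC-NCAC week 4), 5112 (CAC-NCAC week 6), 711 (NCAC-Con week 8), 3942 (CAC-Con weeks 8 to 2), 26 (CAC-Con weeks 8 to 6) and 4015 (CAC-NCAC weeks 8 to 2). Without the degraded library and CAC week 8 replicate 3 the counts moved to 552 (CAC-Con week 2), 186 (CAC-NCAC week 2), 2438 (CAC-Con week 4), 2656 (CAC-NCAC week 4), 7171 (CAC-Con week 6), 7029 (CAC-NCAC week 6), 8268 (CAC-Con week 8), 8810 (CAC-NCAC week 8), 198 (NCAC-Con week 8), 4629 (CAC-Con weeks 8 to 2), 80 (CAC-Con weeks 8 to 6), 5913 (CAC-NCAC weeks 8 to 2) and 6297 (shared by weeks 6 and 8). With voom on recovered reads the counts moved to 13 (CAC-Con week 2), 13 (CAC-NCAC week 2), 2171 (CAC-Con week 4), 1332 (CAC-NCAC week 4), 211 (NCAC-Con week 8), 2493 (CAC-Con weeks 8 to 2) and 2633 (CAC-NCAC weeks 8 to 2). With voom and without the degraded library the counts moved to 35 (CAC-Con week 2), 44 (CAC-NCAC week 2), 3 (NCAC-Con week 2), 1833 (CAC-Con week 4), 2166 (CAC-NCAC week 4), 4932 (CAC-NCAC week 6), 678 (NCAC-Con week 8), 3761 (CAC-Con weeks 8 to 2), 31 (CAC-Con weeks 8 to 6) and 3805 (CAC-NCAC weeks 8 to 2). With an estimated correlation the counts moved to 4 (list tests called). In the rescaled refit with an estimated correlation the counts moved to 0 (list tests called). Leaving out single libraries gave 0 to 5 (CAC-Con week 2), 1 to 14 (CAC-NCAC week 2), 0 to 0 (NCAC-Con week 2), 1883 to 8917 (CAC-Con week 4), 290 to 636 (CAC-NCAC week 4), 0 to 6642 (NCAC-Con week 4), 2407 to 3439 (CAC-Con week 6), 2342 to 3363 (CAC-NCAC week 6), 0 to 0 (NCAC-Con week 6), 3537 to 5237 (CAC-Con week 8), 4302 to 6044 (CAC-NCAC week 8), 0 to 2 (NCAC-Con week 8), 905 to 1826 (CAC-Con weeks 8 to 2), 0 to 4 (CAC-Con weeks 8 to 6) and 1363 to 2484 (CAC-NCAC weeks 8 to 2).

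For the interferon list in NCAC against Con at week 4 the reported test pointed down without a call (camera adjusted p = 0.986) while the median of its members was positive, 0.41. The list was called up with array quality weights (camera adjusted p = 2.94e-12), without the degraded library (camera adjusted p = 8.69e-25) and in the rescaled refit (camera adjusted p = 1.35e-20). With the degraded library the median of all genes was 0.276, and without it 0.01. Leaving out that library alone turned the direction of the list, so the reported direction depended on it. In the refit with an estimated correlation the list was not called (adjusted p = 0.495). No named gene turned its direction past the threshold, but some of the 365 results of named genes changed strength. Without a filter 28 became weaker and 1 stronger, and with voom 22 and 17. With the compared groups fitted alone 19 became weaker and 13 stronger, and with array quality weights 2 and 45. Replicate numbers are the only link between arms, so the replicate block was tried as a check, and moved no other count by over 1.5 times. Over 58 pairs of libraries sharing a number the correlation of residuals lay between -0.275 and 0.411 with a median of 0.005, and 8 of 59 libraries correlated best with their own number.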

Other observations

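Lists and genes of this part were described after the results were seen. In CAC against Con at week 8, ion channel genes moved in both directions. The pacemaker channel gene Hcn2 fell from 17.0 ± 0.866 to 6.60 ± 2.28 TPM. Kcnip2 stood at 26.1 ± 12 TPM in CAC (SD, n = 7) and 88.9 ± 6.87 TPM in Con (SD, n = 5; limma adjusted p = 1.40e-06), and Kcnq1 rose by 1.30 on the log2 scale. Of 24 calcium handling and ion channel genes 4 rose and 3 fell (4 and 3 adjusted over the list alone), and 5 rose and 14 fell in the rescaled refit, with camera adjusted p = 0.0188, direction down, and adjusted p = 0.973 with an estimated correlation. Of 7 ventricular markers 1 fell, Kcnip2, and 0 rose (3 and 0 adjusted over the list alone), with camera adjusted p = 0.00908 and adjusted p = 0.847 with an estimated correlation.

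Of 24 autophagy and lysosome genes 9 rose and 0 fell (9 and 0 adjusted over the list alone), without a call for the list (camera adjusted p = 0.562), and Map1lc3b, Ctsl, Lamp2 and Ctsb rose by 1.09, 1.03, 0.91 and 0.70. Of 31 proteasome subunit genes 7 rose and 0 fell (5 and 0 adjusted over the list alone), without a call for the list (camera adjusted p = 0.534), and Psmd4, Psmc1, Psma7 and Psmb4 rose by 0.60, 0.58, 0.43 and 0.39. Of 20 hypoxia and angiogenesis genes 9 rose and 5 fell (9 and 6 adjusted over the list alone). That list had a median of 0.23, a mean of 0.03 and a test that pointed down without a call (camera adjusted p = 0.235). Pgf rose by 1.64 and Adm by 0.93. Of 6 white adipocyte markers 5 rose and 0 fell (5 and 0 adjusted over the list alone), without a call for the list (camera adjusted p = 0.0831). They were Cfd by 2.06, Car3 by 1.39, Adipoq by 0.84, Lipe by 0.58 and Cidec by 0.57.

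The melanocyte gene Mlana stood at 4.81 ± 2.81 TPM in CAC at week 8 (SD, n = 7), against 0.174 ± 0.0795 TPM in Con and 0.204 ± 0.129 TPM in NCAC (SD, n = 5 each), a log2 fold change of 2.13 against Con (limma adjusted p = 3.61e-13) and 2.10 against NCAC (limma adjusted p = 4.76e-13). In CAC it stood at 0.511 ± 0.213, 1.13 ± 0.423 and 2.58 ± 0.895 TPM at weeks 2, 4 and 6 (SD, n = 5 each). Pmel reached at most 0.469 TPM in any CAC week 8 library, and Dct fell from 3.04 ± 0.713 TPM in Con to 1.02 ± 0.634 TPM in CAC (limma adjusted p = 4.59e-04). Gdf15, a cytokine gene linked to loss of appetite, rose from 0.909 ± 0.283 to 3.13 ± 1.51 TPM against Con (limma adjusted p = 1.94e-04), and Il6 stood at 0.158 ± 0.107 against 0.00776 ± 0.0106 TPM and was not tested because of its low level.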
